A study of Mus musculus with 26 samples.

How the data were processed

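The series holds 26 mouse skin cell lines, each measured on 1 Affymetrix M430 array. Per the labels' protocols, the lines were grown in serum, total RNA was taken in log phase with Trizol and a column clean-up, and biotin-labelled cRNA was hybridised. Nothing in the labels shows more than 1 culture per line, so p-values measure the spread between lines, not between cultures of a line. They take lines as independent, although some share a name family or lie close to each other. The number of arrays limits the precision of each group mean.

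The deposited table holds log2 values made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalises the arrays and summarises the probes of each probe set. Its version, software and probe set definitions are not given in the sources used here. The table has 45037 probe sets and values from 2.28 to 14.92. Quantile normalisation forces near-equal distributions on all arrays, so a change in total RNA per cell cannot be seen, and values near the lower end are background, where a fold change is compressed. Probe sets were named through a table of probe sets and genes. A single gene symbol was found for 34945 probe sets and several symbols for 932, while 9160 stayed unnamed here. A current gene ID was matched for 34741 of the single-gene probe sets in the RefSeq annotation of GRCm38.p6, which was used for names only. No genome coordinates are printed, because the files name no build.

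Lines were grouped by their cell type label and the keratinocyte, papilloma and spindle flags. A line entered a group only where label and flag agreed. This gave 2 keratinocyte lines, 12 carcinoma lines without spindle pathology, 7 carcinoma lines with it and 1 papilloma line. Left out of every comparison were 2 carcinoma lines whose spindle flag is not stated, 1 carcinoma line whose label and flag conflict, and 1 keratinocyte line whose label and flag conflict. Their values are given line by line. Replicate numbers were given in the order of deposition and pair nothing.

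Each gene was represented by its probe set with the highest mean over all arrays, which gave 18193 genes. Genes above the array's median over all probe sets on 2 or more arrays were tested, which left 12641. Group means were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) in 1 model of the 3 main groups, with 21 lines. The Spretus-cross comparison was fitted in the 12 non-spindle lines alone. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and all adjusted p-values of genes are from limma. Fold changes are given on the log2 scale with limma's standard error (SE).

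Gene lists were written before the data were examined: 27 lists with 502 entries, of which 38 had no single-gene probe set here and were not analysed. Lists with 5 or more measured genes were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. camera compares a list with the other genes. fry asks whether the genes of a list move, on balance, one way. The epithelial minus mesenchymal index of a line is the mean log2 value of 26 epithelial junction genes minus that of 25 mesenchymal genes. It was compared with a two-sided exact permutation test over all 50388 divisions of the lines. The 26 and 25 genes are the members of the lists that passed the filter.

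The genes named were chosen by a rule set before the data were examined. For each comparison they are the 6 called genes with the largest rise and the 6 with the largest fall, and up to 3 called members of each list. Every measured member of the lists of mouse skin tumour genes, EMT transcription factors and sex-linked genes was also open to naming, called or not. The planned values of genes named in some titles and descriptions are not reported here.

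The fit was also tested on simulated values with the real gene means and spreads, in which 200 of 12641 genes were changed. For spindle against non-spindle lines it recovered 93% of changes of 2 log2 units and 99% of changes of 4. For non-spindle against keratinocyte lines the shares were 75% and 95%, for spindle against keratinocyte lines 75% and 90%, and for the Spretus-cross comparison 88% and 94%. With no change put in, 0 genes were called in each comparison. Among the calls made with changes put in, 13 of 205 were false for spindle against non-spindle lines. The false calls were 10 of 180 for non-spindle against keratinocyte lines, 16 of 181 for spindle against keratinocyte lines and 4 of 186 for the Spretus-cross comparison. On simulated lists for spindle against non-spindle lines, camera under both correlations and fry each called the 1 shifted list and 0 of 19 others. These simulated values were normal and drawn independently for each line, so they hold no families of lines and no structure within a group. Genes were drawn independently too, so the simulated lists cannot show how camera at the preset correlation behaves on correlated genes. The estimated correlation of the measured epithelial junction genes was 0.585.

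Alternatives set before the data were examined covered the choice and kind of probe set, the filter, quantile normalisation or median centring of the deposited values, eBayes with trend, array weights, and a 2-fold minimum. They also covered averaging or blocking lines of 1 name family, other places for the lines with conflicting labels, and leaving out each line. Alternatives added after seeing the data left out 3 lines that lack epithelial transcripts, averaged arrays that lie closer than any pair of 1 name family, and left out the PDV, MSCP1 and B9ras arrays from the Spretus-cross comparison. Figures and tables were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.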

Results

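Transcript levels were measured in 26 mouse skin cell lines that stand for stages of skin tumour development, from immortalised keratinocytes to carcinoma. The keratinocyte lines were C5N and NK (n = 2), and P6 was the papilloma line. The carcinoma lines without spindle pathology were PDV, SN161, B9ras, B9rassmad, MSCP5, MSC12, MSCP1, MSC11B, PDVC57, E4, B9 and MSC7A (n = 12). The carcinoma lines with spindle pathology, an elongated and fibroblast-like form of squamous carcinoma, were D3, D3DP, A5, MSN2, H11, CarC and CarB (n = 7). The spindle state was not stated for 2945CA and MSCb1, and the labels conflicted for B9Smad and for 1 keratinocyte line. All values are log2 RMA values of 1 array per line, and errors are SDs between lines unless an SE is named.

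The first comparison asked which transcripts differ between carcinoma lines with and without spindle pathology. Igfbp3, a secreted binder of insulin-like growth factors, fell by 5.82 on the log2 scale (SE 1.07), from 10.54 ± 2.86 (n = 12) in non-spindle lines to 4.72 ± 1.08 (n = 7) in spindle lines. Fat1, an atypical cadherin, fell by 1.81 on the log2 scale (SE 0.27), and its highest spindle value of 11.06 lay below its lowest non-spindle value of 11.34. Khdrbs3, an RNA-binding splicing regulator, rose by 3.63 (SE 0.67), or 12.3-fold. Rps6ka3, a kinase downstream of ERK, rose by 1.04 (SE 0.19), and Pdhb, a subunit of pyruvate dehydrogenase, rose by 0.84 (SE 0.15).

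With Thap2 (1.37 higher), Dennd6a (0.84 higher) and Hnrnph3 (0.70 higher), these made up the 8 genes called among 12641, 6 higher and 2 lower in spindle lines. Their adjusted p ranged from 0.00581 for Thap2 to 0.044 for Khdrbs3, 5 of them changed 2-fold or more, and 2611 genes had an unadjusted p under 0.05. Without MSC12, MSC11B and MSC7A, 3 non-spindle lines set apart only after their values were seen, 1954 genes were called, 1058 higher and 896 lower. Of the 170 divisions of the carcinoma lines that keep lines of 1 name family and close arrays together, 68 gave 8 or more genes, so a count of 8 does not set spindle pathology apart from other divisions of related lines. Fat1 and Thap2 stayed called with the name family as a random block (adjusted p = 0.0235 and 0.0165) and without any single line, and the other 6 genes did not. With name families averaged Fat1 alone was called (adjusted p = 0.0415), and with close arrays averaged, an alternative added after seeing the data, 0 of the 8 were (limma adjusted p of 0.181 or more). With the lines of conflicting labels placed by cell type label, limma called 0 genes, so Fat1 and Thap2 were lost there too. Leaving out 1 line moved the count to 471 without MSC11B, 183 without MSC7A, 179 without MSC12, 5 without CarC, 4 without B9rassmad or E4, 3 without D3, A5, MSN2 or PDVC57, and 2 without PDV, SN161, B9ras, MSCP1, D3DP, H11 or CarB.

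Epithelial genes were lower in spindle lines as groups by camera at the preset correlation, and whether single members were called depended on MSC12, MSC11B and MSC7A. Of 26 measured epithelial junction genes, 0 were called over all genes and 16 were lower when adjusted over the list alone, with a median log2 fold change of -1.58. Cdh1, the gene of E-cadherin, was at 3.43 ± 0.30 (n = 7) in spindle and 9.13 ± 3.56 (n = 12) in non-spindle lines, a difference of -5.70 (SE 1.26) with a limma adjusted p of 0.0542. Grhl2, a transcription factor that maintains epithelial junctions, differed by -2.62 (SE 0.61, adjusted p = 0.0632). Among desmosome genes, 0 of 12 were called over all genes and 9 were lower when adjusted over the list alone. For basal and simple keratins these counts were 0 of 13 and 6, and for basal epidermal and stem cell regulators 0 of 19 and 7, all lower. camera called the epithelial junction list (adjusted p = 3.24e-15), but adjusted p = 0.351 with an estimated correlation. The desmosome (7.57e-06), keratin (1.31e-05) and basal epidermal (4.25e-05) lists were called by camera too, each with adjusted p = 0.351 with an estimated correlation. The squamous differentiation list was lower by camera (adjusted p = 0.000156) with 0 of 22 genes called either way, and had adjusted p = 0.535 with an estimated correlation. fry called 0 of 25 lists, with a lowest adjusted p of 0.0619. Without MSC12, MSC11B and MSC7A, 17 epithelial junction, 10 desmosome, 7 keratin and 9 basal epidermal genes were called over all genes, each of them lower. With an estimated correlation the epithelial junction and keratin lists then each had adjusted p = 0.0244, and the desmosome and basal epidermal lists adjusted p = 0.0574. The 3 lines were chosen for lacking epithelial transcripts, so lower epithelial genes in that setting follow from the choice and are no test of them.

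Calls among mesenchymal genes also depended on these 3 lines. Of 25 measured, 0 were called over all genes and 1, lower in spindle lines, when adjusted over the list alone, although the median log2 fold change was 1.00. camera gave this list an adjusted p of 0.256, and the fibroblast marker list, with a median of 1.12, an adjusted p of 0.13. Of 12 EMT transcription factors, 0 were called over all genes and 4 when adjusted over the list alone, 3 higher and 1 lower. Zeb1 differed by 2.29 (SE 0.69, adjusted p = 0.109) and Twist1 by 1.27 (SE 0.47, adjusted p = 0.15), while Snai2 differed by -0.07 (SE 0.47). Without the 3 lines, 6 mesenchymal genes were higher and 1 lower over all genes, with a median of 2.07, camera adjusted p = 0.00226 and adjusted p = 0.553 with an estimated correlation. In that setting 4 EMT transcription factors were higher and 1 lower, with camera adjusted p = 0.222, and fibroblast markers had 3 genes higher with camera adjusted p = 0.00802 and adjusted p = 0.367 with an estimated correlation. MSC12, MSC11B and MSC7A had mesenchymal means of 11.12, 10.14 and 11.37, against 10.47 in MSCP5 and at most 7.13 in the other non-spindle lines. Higher values of these 3 lists in spindle lines thus follow from leaving them out and are no test. The interferon response list was higher by camera (adjusted p = 0.000444) with a median of 0.85, 0 of 21 genes called over all genes and 0 adjusted over the list alone. It had adjusted p = 0.552 with an estimated correlation.

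Genes known from mouse skin tumours were lower as a list in spindle lines by camera (adjusted p = 0.0428), with adjusted p = 0.351 with an estimated correlation. Of 20 measured, 0 were called over all genes and 4 were lower when adjusted over the list alone. Fst, which encodes the activin antagonist follistatin, differed by -3.55 (SE 0.94, adjusted p = 0.0861) and the integrin gene Itgb4 by -3.40 (SE 1.02, adjusted p = 0.106). Cdkn2a, the Ink4a and Arf gene, differed by -0.02 (SE 0.77), Met by -0.38 (SE 0.50) and Ccnd1 by -0.18 (SE 0.37). The small Cdkn2a difference averages unlike lines, since CarC and CarB were at 4.37 and 3.98 and the other spindle lines at 8.39 to 9.42. Cdkn2b was likewise at 4.81 and 4.4 in CarC and CarB, against 9.48 to 10.76 in the other spindle lines. Of 23 genes of the Ras and MAP kinase pathway and its feedback, 0 were called over all genes and 7 when adjusted over the list alone, 2 higher and 5 lower. camera called that list as lower (adjusted p = 0.0428), with adjusted p = 0.424 with an estimated correlation.

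**Figure D1:**
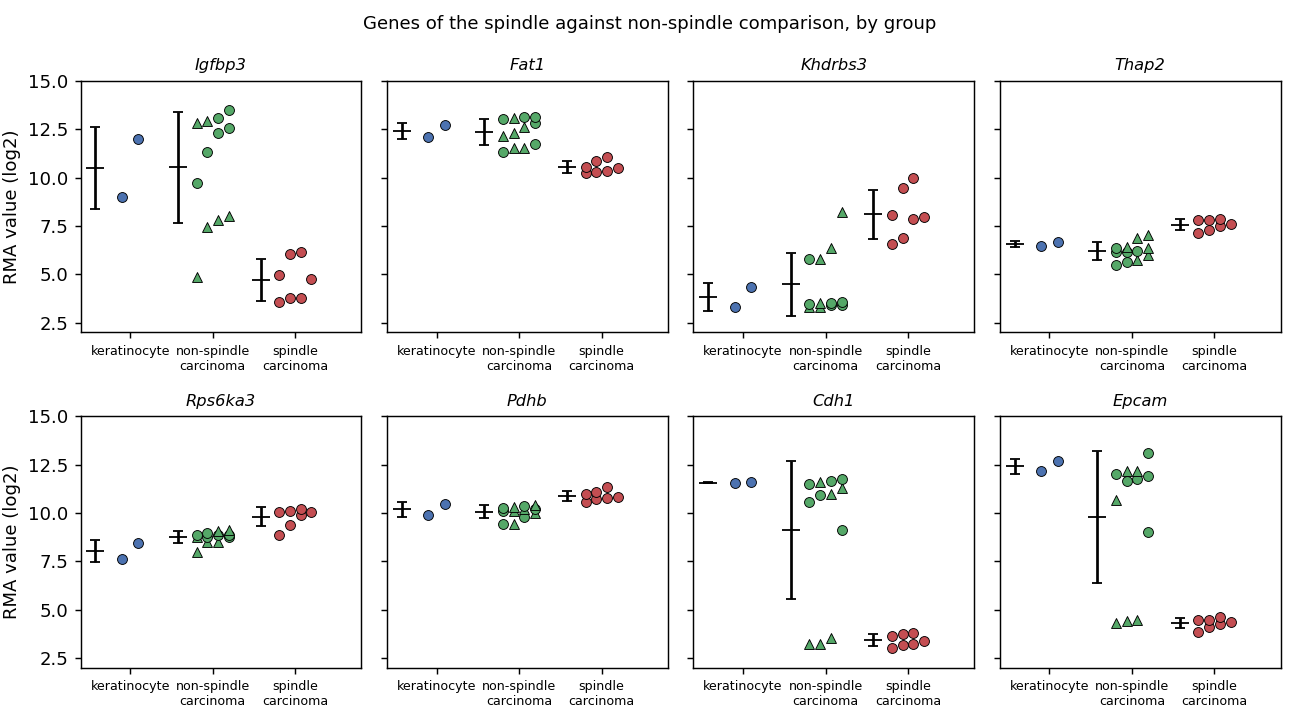
Log2 RMA values (vertical axis) of 8 genes in keratinocyte, non-spindle carcinoma and spindle carcinoma lines (horizontal axis); each point is 1 line, triangles are lines from a Spretus cross, and bars are the group mean ± SD. Fat1 is at 11.06 or below in all 7 spindle lines, and 3 non-spindle lines, with Cdh1 at 3.25 to 3.54, lie among the spindle lines for Cdh1 and Epcam.

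The epithelial minus mesenchymal index put the same question as 1 value per line. It averaged -3.45 ± 1.38 (n = 7) in spindle lines and -0.58 ± 3.61 (n = 12) in non-spindle lines, a difference of -2.87 that did not pass the two-sided exact permutation test (p = 0.0625). The keratinocyte lines averaged 2.69 ± 0.52 (n = 2). Among non-spindle lines the index ran from 3.70 in B9 to -6.44 in MSC7A, with -6.34 in MSC12 and -5.16 in MSC11B, so these 3 lines were lower than 6 or more of the 7 spindle lines. In the same 3 lines Cdh1 was at 3.25, 3.25 and 3.54, against 9.13 to 11.78 in the other 9 non-spindle lines. Without 1 of these lines the exact p was 0.022 for MSC12, 0.0326 for MSC11B and 0.0212 for MSC7A.

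**Figure D2:**
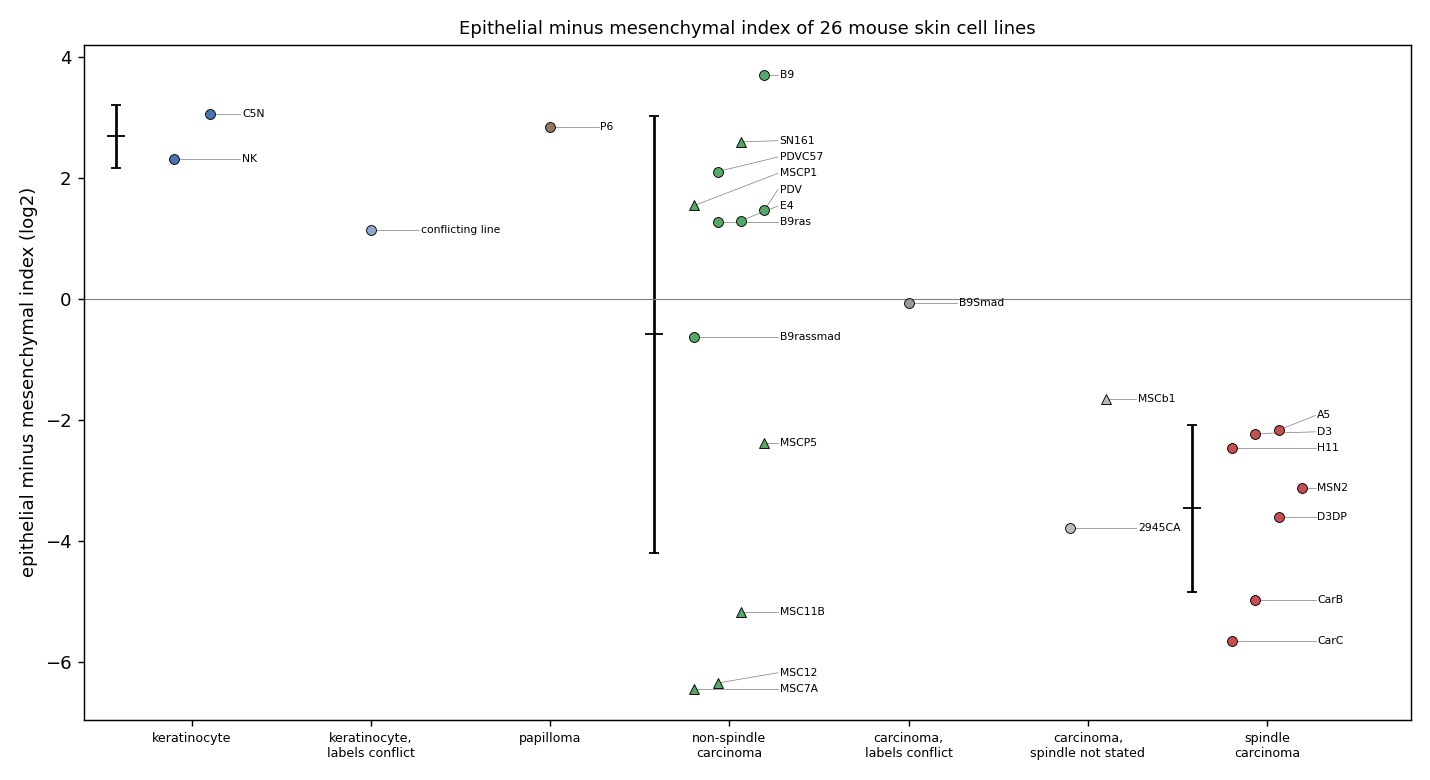
Epithelial minus mesenchymal index (vertical axis, log2) of all 26 lines by group (horizontal axis); each point is 1 named line, triangles are lines from a Spretus cross, and bars are the mean ± SD of the 3 groups compared. The spindle lines lie between -5.64 and -2.16, and MSC12, MSC11B and MSC7A lie at -5.16 or below although their labels place them with the non-spindle lines.

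The second comparison set the non-spindle carcinoma lines against immortalised keratinocytes. Igfbp2, another binder of insulin-like growth factors, fell by 7.14 on the log2 scale (SE 1.37), from 12.16 ± 0.38 (n = 2) to 5.02 ± 2.42 (n = 12). Gpx2, an epithelial glutathione peroxidase, fell by 5.12 on the log2 scale (SE 1.02). The chromatin protein gene Hmga2 rose by 4.93 (SE 0.80), from 6.50 ± 2.16 (n = 2) to 11.44 ± 0.85 (n = 12), and the EMT transcription factor genes Twist2 and Zeb2 rose by 4.27 (SE 0.79) and 3.26 (SE 0.81). Fosl1, an AP-1 subunit induced by ERK signalling, rose by 3.21 (SE 0.50), and the MHC class I genes H2-D1 and H2-K1 rose by 3.71 (SE 0.76) and 3.38 (SE 0.68). The H2-D1 and H2-K1 values ran close together, at 5.83 and 5.94 in C5N and at 8.94 and 8.61 in NK. Whether their probe sets read separate transcripts was not tested.

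In all, 255 genes were called, 112 higher and 143 lower in carcinoma lines, and 222 of them changed 2-fold or more. The count was 163 with conflicting lines placed by cell type label, and 150 with close arrays averaged, an alternative added after seeing the data. The largest rises besides those named above were in Fbln2 (6.27), which encodes a matrix fibulin, Aldh2 (5.78), Gusb (5.70), Flot2 (5.56), Cavin2 (5.08) and Thbd (4.99). Fbln2, Aldh2, Gusb, Flot2 and Thbd are among 15 genes below the array median in both keratinocyte lines and above it in every non-spindle line. For part of the 15 a loss of probe signal was not excluded, and leaving out either keratinocyte line cannot show such a loss. Other probe sets gave 1.41 for Flot2, at most 1.49 for Aldh2 and 5.09 for Gusb. The largest falls included Wfdc18 (-5.39), Chl1 (-5.27), Spink12 (-4.69) and Bpifc (-4.54). The keratinocyte lines differed widely in some genes, so that values without C5N were 1.64 for Ereg, 2.15 for H2-D1, 2.04 for H2-K1, -1.64 for Prss8, -2.74 for Spink12 and -2.33 for Wfdc18. Without NK, Ereg was 5.98 higher and Wfdc18 differed by -8.45. Of the 27 called genes open to naming, 9 stayed called without C5N and 12 without NK. The 5 that stayed called in both fits were Gusb, Flot2, Wfdc18, Bpifc and Marveld3. The count was 147 without C5N, which leaves NK as the sole keratinocyte line, assumed to vary like the other groups, and 240 without MSC12, MSC11B and MSC7A. Lce1a1, a cornified envelope gene that fell by 1.58 on the log2 scale (SE 0.40), was at 8.28 in NK and 5.06 in C5N, and its difference was 0.03 without NK and -3.18 without C5N.

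EMT transcription factors rose as named above in 3 of 12 measured, with the same count adjusted over the list alone. Twist2 and Zeb2 were both low in the keratinocyte lines, Twist2 at 4.87 and 4.99 and Zeb2 at 3.51 and 4.03. Twist2 is also 1 of 15 genes that were above the array median in every non-spindle line and below it in both keratinocyte lines, for which a loss of probe signal was not excluded. camera gave this list an adjusted p of 0.00922, and adjusted p = 0.28 with an estimated correlation. In the Ras and MAP kinase list 4 of 23 genes rose, again 4 adjusted over the list alone, among them the growth factor gene Ereg (3.81, SE 0.80) and the ERK phosphatase gene Dusp4 (2.30, SE 0.50). That list had a camera adjusted p of 0.0104, and adjusted p = 0.28 with an estimated correlation. The MHC class I list had 2 of 9 genes higher over all genes and adjusted over the list alone, a camera adjusted p of 0.0104, and adjusted p = 0.349 with an estimated correlation. The 2 are H2-D1 and H2-K1, which may not be separate signals. Of 24 TGF-beta pathway genes 1 rose, Tgfb1 (1.34, SE 0.33), and 5 were higher when adjusted over the list alone, with camera adjusted p = 0.0421 and adjusted p = 0.28 with an estimated correlation. Timp1, an inhibitor of matrix proteases, rose by 2.21 (SE 0.47), and the receptor kinase gene Axl by 2.13 (SE 0.40).

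Epithelial junction genes fell in 3 of 26 measured, and 7 were lower when adjusted over the list alone. The 3 were Marveld3 (-3.44, SE 0.43), Grhl3 (-2.90, SE 0.71) and Prss8 (-2.50, SE 0.48). camera gave the list an adjusted p of 4.72e-08, and adjusted p = 0.28 with an estimated correlation. Squamous differentiation genes had 1 of 22 lower over all genes, Lce1a1, and 2 adjusted over the list alone, with camera adjusted p = 1.68e-06 and adjusted p = 0.28 with an estimated correlation. Cdh1 itself differed by -2.45 (SE 2.02, adjusted p = 0.743). Of 25 mesenchymal genes 0 were called over all genes and 0 adjusted over the list alone, with a median of 1.86, camera adjusted p = 0.0104 and adjusted p = 0.564 with an estimated correlation. Fibroblast markers were higher beside these groups: 1 of 10 rose over all genes and adjusted over the list alone, with camera adjusted p = 0.0104 and adjusted p = 0.349 with an estimated correlation. Without MSC12, MSC11B and MSC7A the mesenchymal median was 0.78 (camera adjusted p = 0.232) and the fibroblast marker median 1.06 (camera adjusted p = 0.0766), so both list calls rest on those lines. The TGF-beta (camera adjusted p = 0.0851) and desmosome (0.188) list calls were lost there too, and 2 EMT transcription factors were called in place of 3. camera called 13 of 25 lists in all, 10 higher and 3 lower, and fry called 0, with a lowest adjusted p of 0.0779.

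The third comparison set the spindle carcinoma lines against the same keratinocyte lines, so overlaps between its calls and those of the second comparison are not read as a shared effect. The keratin genes Krt14 and Krt17 fell by 9.68 on the log2 scale (SE 2.49) and by 9.29 (SE 2.49), with Krt14 at 14.05 ± 0.10 (n = 2) in keratinocytes and 4.37 ± 0.22 (n = 7) in spindle lines. The SEs and calls of this comparison use a spread pooled over all 3 groups. They thus carry the spread of the non-spindle lines, where Krt14 ran from 4.07 in MSC12 to 14.51 in MSCP1. No fit without MSC12, MSC11B and MSC7A was run for this comparison. Cdh1 fell by 8.15 (SE 2.12), Epcam, an epithelial adhesion gene, by 8.13 (SE 2.03), and the epithelial splicing regulator gene Esrp1 by 6.83 (SE 1.74). Pcolce, an enhancer of procollagen processing, rose by 8.47 (SE 2.22) to 13.17 ± 0.44 (n = 7). The nuclear receptor gene Nr2f1 rose by 6.89 (SE 0.99), and the TGF-beta co-receptor gene Tgfbr3 by 5.90 (SE 1.08). Nr2f1, Aldh2 and Twist2 are among the 15 genes for which a loss of probe signal in the keratinocyte lines was not excluded.

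In all, 676 genes were called, 303 higher and 373 lower in spindle lines, and 600 of them changed 2-fold or more. The other largest changes were rises of Aldh2 (6.77), Cavin2 (6.63), Aqp1 (6.56) and Nrn1 (6.03), and falls of Dmkn (-9.15) and Igfbp2 (-8.40). Of the 46 called genes open to naming, 10 stayed called without C5N and 11 without NK. The 5 that stayed called in both fits were Nr2f1, Aldh2, Igfbp2, Twist2 and Fosl1. Among the genes given here, the values that moved by over 1.5 times were those of Ereg, 0.96 without C5N and 5.30 without NK, Twist1 (1.86 without C5N), Hmga2 (2.97), H2-D1 (2.46) and H2-K1 (2.34). The count of all genes was 258 without C5N and 284 without NK, in fits where the sole keratinocyte line is assumed to vary like the other groups. Averaging close arrays, an alternative added after seeing the data, gave 323.

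Epithelial junction genes fell in 15 of 26 measured, and 21 were lower when adjusted over the list alone. camera gave the list an adjusted p of 6.38e-18, adjusted p = 0.38 with an estimated correlation, and fry an adjusted p of 0.0113. Desmosome genes fell in 4 of 12, among them Pkp1 (-5.15, SE 1.32), Jup (-3.90, SE 0.96) and Ppl (-3.81, SE 0.99), and adjusted over the list alone 8 were lower and 1 higher. For desmosomes camera gave adjusted p = 3.54e-05, adjusted p = 0.38 with an estimated correlation, and fry 0.0334. Squamous differentiation genes fell in 5 of 22, including Spink5 (-6.82, SE 1.71) and Sbsn (-5.69, SE 1.47), and 13 were lower when adjusted over the list alone. This list had camera adjusted p = 4.05e-09, adjusted p = 0.38 with an estimated correlation, and fry 0.0334. Basal and simple keratins fell in 3 of 13, the third being Krt6a (-7.64, SE 2.20), and 7 were lower adjusted over the list alone, with camera adjusted p = 0.00222 and adjusted p = 0.397 with an estimated correlation. The keratin list was not called by fry (adjusted p = 0.0817).

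EMT transcription factors moved with them: 4 of 12 rose and 1 fell over all genes, and 6 were higher and 1 lower when adjusted over the list alone. Twist2 rose by 4.80 (SE 0.83), Hmga2 by 4.50 (SE 0.84), Zeb2 by 4.03 (SE 0.85) and Twist1 by 3.13 (SE 0.79), and Grhl2 fell by 4.29 on the log2 scale (SE 1.03). This list had camera adjusted p = 0.0105, adjusted p = 0.38 with an estimated correlation, and fry 0.0267. Of 25 mesenchymal genes, S100a4 rose by 5.01 (SE 1.35) and Tnc, which encodes the matrix protein tenascin C, fell by 6.32 on the log2 scale (SE 1.67). Adjusted over the list alone, 2 mesenchymal genes were higher and 1 lower, with camera adjusted p = 0.0076, adjusted p = 0.624 with an estimated correlation, and fry 0.277. Fibroblast markers had 1 of 10 genes higher over all genes and 3 adjusted over the list alone, with camera adjusted p = 0.00503, adjusted p = 0.397 with an estimated correlation, and fry 0.068.

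In the signalling lists, Fosl1 rose by 3.76 (SE 0.52) and Ereg by 3.13 (SE 0.84), while the receptor gene Erbb3 fell by 4.11 on the log2 scale (SE 1.15). Of 23 Ras and MAP kinase genes 4 rose and 2 fell, and adjusted over the list alone 5 were higher and 3 lower, with camera adjusted p = 0.425. Tgfb3 (3.12, SE 0.75) and Smad3 (1.36, SE 0.29) rose with Tgfbr3 among 24 TGF-beta pathway genes, of which 4 were higher and 1 lower when adjusted over the list alone, with camera adjusted p = 0.425. H2-D1 (4.01, SE 0.80) and H2-K1 (3.68, SE 0.71) rose among 9 MHC class I genes, 4 of them adjusted over the list alone. Whether the probe sets of H2-D1 and H2-K1 read separate transcripts was not tested. The MHC list had camera adjusted p = 0.00222, adjusted p = 0.397 with an estimated correlation, and fry 0.0334. The hypoxia gene Bnip3 rose by 3.06 (SE 0.58) and the glutathione transferase gene Gstp1 by 1.79 (SE 0.47). Fst fell by 6.42 on the log2 scale (SE 1.59). camera called 10 of 25 lists, 5 higher and 5 lower, and fry called 7.

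**Figure D3:**
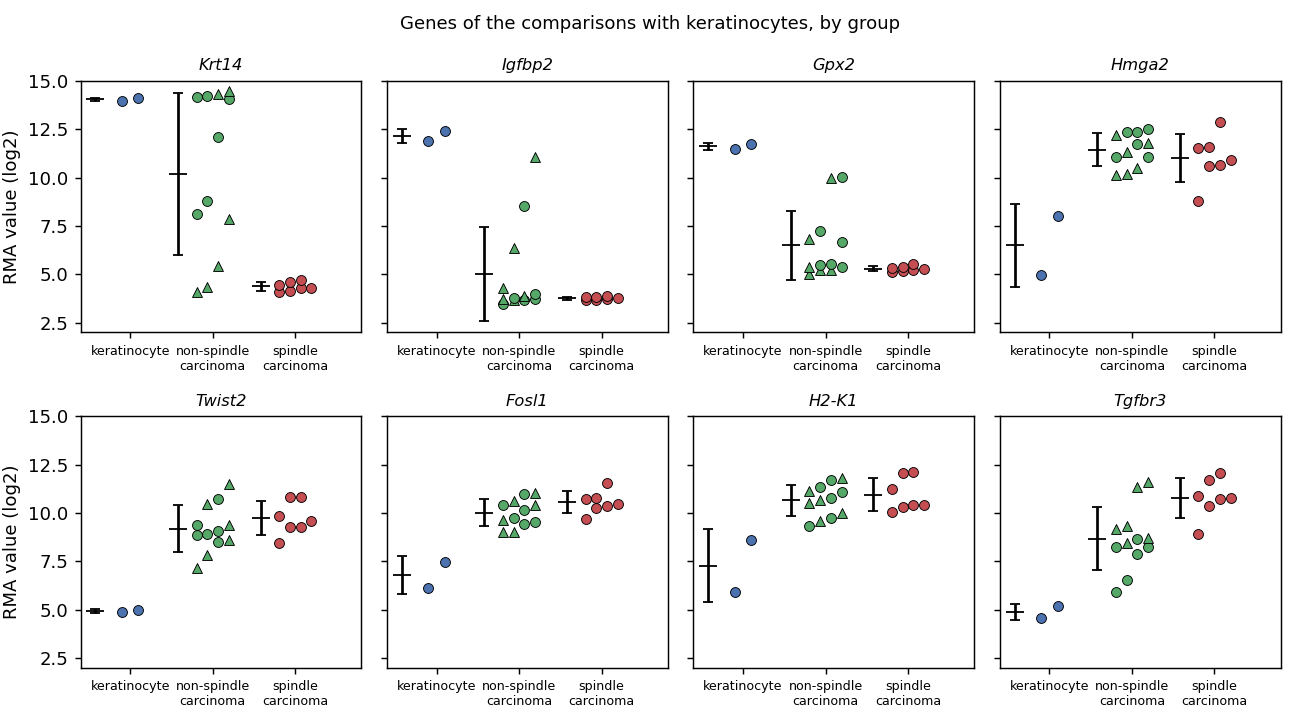
Log2 RMA values (vertical axis) of 8 genes in keratinocyte, non-spindle carcinoma and spindle carcinoma lines (horizontal axis); each point is 1 line, triangles are lines from a Spretus cross, and bars are the group mean ± SD. Krt14 is at 14.05 in keratinocytes and 4.37 in spindle lines on average, and Hmga2 and Twist2 are higher in both carcinoma groups than in keratinocytes.

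The last comparison asked whether non-spindle lines from tumours of a Spretus cross (n = 6), a cross between mouse species, differ from those with no cross stated (n = 6). limma called 0 genes, with 1383 at an unadjusted p under 0.05, and limma with array weights called 304. Snai1 differed by 2.51 (SE 0.69), Zeb1 by 2.33 (SE 0.81) and the simple keratin gene Krt8 by -4.78 (SE 1.61), each with an adjusted p of 0.417. Leaving out MSCP1 gave 163 calls, 113 higher and 50 lower in the cross lines, and leaving out any other single line gave 0, as did leaving out PDV, MSCP1 and B9ras together (limma, 1591 genes at an unadjusted p under 0.05). Of 25 mesenchymal genes, 0 were called over all genes and 15 were higher in the cross lines when adjusted over the list alone, with a median of 3.03. camera gave this list an adjusted p of 2.91e-11, and adjusted p = 0.361 with an estimated correlation. Fibroblast markers had 0 of 10 genes called over all genes and 3 higher when adjusted over the list alone, with camera adjusted p = 0.00155 and adjusted p = 0.361 with an estimated correlation. The interferon response list was higher (median 0.59, camera adjusted p = 1.62e-07) and the proliferation list lower (median -0.33, camera adjusted p = 1.65e-05), each with adjusted p = 0.361 with an estimated correlation. In both lists 0 of 21 genes were called over all genes and 0 when adjusted over the list alone. camera called 15 of 25 lists, 7 higher and 8 lower, and fry called 0, with a lowest adjusted p of 0.144. The index averaged -2.69 ± 3.99 in cross lines and 1.54 ± 1.40 in the others (exact permutation test over 924 divisions, two-sided, p = 0.0455), a test added to the plan. The 924 divisions take lines as independent. Yet PDV, PDVC57, B9, B9ras and B9rassmad are joined by name family or close arrays, together with MSCP1 of the cross lines. No test of the index kept these lines together. Without MSC12, MSC11B and MSC7A the difference shrank from -4.23 to -0.95 (exact p = 0.5), which is no test, since these lines were chosen for low values of genes in the index. The index difference also missed the threshold without any 1 of 9 lines, with exact p = 0.0584 without PDV, B9ras or E4, 0.0628 without PDVC57, 0.0758 without MSCP5, MSC11B or B9, and 0.0801 without MSC12 or MSC7A. MSC12, MSC11B and MSC7A make up 3 of the 6 cross lines. Without them limma called 0 genes, with 482 at an unadjusted p under 0.05. In that setting the fibroblast marker median was 0.65 (camera adjusted p = 0.458), the mesenchymal median 1.29 (camera adjusted p = 3.43e-05, adjusted p = 0.503 with an estimated correlation), and the epithelial junction median turned from -1.08 to 0.25. The labels give no cross for any spindle line, and spindle lines against the 6 non-spindle lines with no cross stated gave 1603 genes. That setting also leaves out MSC12, MSC11B and MSC7A. All but E4 of its 6 non-spindle lines are joined by name family or close arrays, and the fit takes them as independent.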

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

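Values of the genes open to naming were tested for single lines far from the rest in the spindle group and in the Spretus-cross and other non-spindle lines. Of 157 groups of values, 16 held such a line, and chance gives about 1 in 20. Of the tests weighed here, those on strain variants, swapped labels and divisions of related lines were chosen only after the result was seen, as was the setting without 3 lines.

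Among spindle lines, Smad2, a transducer of TGF-beta signals, was at 11.97 in D3DP and between 8.07 and 8.90 in the other lines. CarC was set apart in Aurka (7.79, others 9.95 to 10.78), Sema3d (6.0, others 3.36 to 3.75), Smad4 (11.25, others 10.37 to 10.70) and Timp1 (10.04, others 10.97 to 11.52). The low Aurka value was not isolated, since the mean of the proliferation list was 7.92 in CarC and 10.4 to 10.91 in the other spindle lines. The cause was not tested. Krt13 was at 7.23 in MSN2 against at most 4.27 elsewhere, Tubb3 at 6.62 in D3 against at most 5.49, and Twist1 at 9.27 in CarB against at most 8.71.

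Among Spretus-cross lines, Egfr was at 8.85 in MSCP1 (others 7.11 to 7.76), the gap junction gene Gjb2 at 8.08 in MSCP5 (others 3.83 to 4.42), and the Y-linked Kdm5d at 7.88 in MSC11B (others 2.98 to 3.09). Among lines with no cross stated, B9 was set apart in Foxc2 (4.24, others 8.23 to 8.91) and Gjb2 (4.83, others 3.83 to 4.0). PDVC57 was set apart in Vdr (4.63, others 5.21 to 5.51) and Xist (5.73, others 10.73 to 13.15), and E4 in Zeb1 (7.88, others 5.05 to 6.01). Vdr in PDVC57 and Gjb2 in B9 were below the medians of their arrays, 5.144 and 5.147, so both differences lie near background.

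The first pattern weighed is that MSC12, MSC11B and MSC7A, labelled as non-spindle, lack epithelial transcripts. Strain variants under the probes are argued against as the whole cause, since the lowest epithelial junction mean of the Spretus-cross lines SN161 and MSCP5 was 3.09 log2 units above the highest of the 3 lines. A swap with the 7 spindle lines compared is argued against too, since 0 of 7 had a mean in the range of the other 9 non-spindle lines. That count leaves out B9Smad, labelled as spindle but not by its flag. Its mean of 6.52 lay within that range of 6.5 to 9.42, so a swap of a single line with B9Smad stays open. Fibroblasts in place of tumour cells stay open: 0 of the 3 lines had a fibroblast marker mean above every spindle line, but spindle lines carry these markers themselves, up to 10.82 in CarC against 10.69 in MSC12, so the bound set beforehand, which read 0 as evidence against, was dropped after the values were seen. A wrong spindle flag for single lines, or a mesenchymal state of carcinoma cells that the flag does not record, may also account for it, and neither was tested. MSC11B lay close to the spindle lines MSN2 (Pearson r = 0.983 across probe sets, 1414 of them 2-fold apart) and D3DP (r = 0.981). For comparison, the closest pair of 1 name family had r = 0.984. The cause of the likeness of MSC11B to these spindle lines was not tested. Without the 3 lines, spindle against non-spindle gave 1954 genes in place of 8.

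The second pattern is that the MSCP1 array, labelled as from a Spretus cross, lay closer to PDV (Pearson r = 0.991 across probe sets, 391 of them 2-fold apart) than any pair of 1 name family, of which the closest had r = 0.984. The same holds for B9ras and MSCP1 (r = 0.988, 819 probe sets 2-fold apart), for PDV and B9ras (r = 0.990), for D3DP and MSN2 (r = 0.987), and for A5 and H11 (r = 0.993, 399 probe sets 2-fold apart), and the spindle group counts A5 and H11 as separate lines. An array that does not hold cells of a Spretus cross was tested with a score on probe sets that separate Spretus-labelled from other lines within a gene. MSCP1 scored -1.84, which met the bound set beforehand for this explanation, but after the values were seen the test was judged void, since the other labelled lines at -1.26 to 1.45 overlapped with the lines with no cross stated at -2.07 to 0.84. A candidate explanation is a relabelled or shared culture, and a real likeness of separate carcinoma lines cannot be told apart from it here. Leaving out MSCP1 raised the Spretus-cross count from 0 to 163, whereas leaving out PDV, MSCP1 and B9ras together, a setting added after seeing the data, kept it at 0.

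The third pattern is a set of 15 genes below the array median in both keratinocyte lines and above it in every non-spindle line, Gusb, Flot2 and the EMT transcription factor gene Twist2 among them. Loss of signal at single probe sets, such as from a strain variant, was tested on 11 other probe sets of 8 of these genes. Their median log2 fold change was 1.49 against 4.88 for the tested ones, a ratio of 0.31, but this decides nothing, since 3 of the 11, of Fbln2 and Aldh2, were at or below the mean array median in non-spindle lines too and cannot show a rise. The 8 others, looked at after this was seen, had a median of 2.48 against 4.20, and 5 genes had another probe set that kept more of the log2 fold than it lost: Gusb (5.09 against 5.70), Plod2 (3.33 against 4.20), Stk39 (3.26 against 2.77), Atp10a (2.69 against 3.05) and Car5b (1.19 against 2.26). That of Flot2 gave 1.41 against 5.56 and the third of Aldh2 1.49 against 5.78, so loss of signal stays open for part of the set. Twist2 and Nr2f1 had no other expressed probe set. The design names a biological difference, carcinoma against keratinocyte, which stays open too.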

How the results depend on the processing

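The settings without 3 lines, with close arrays averaged, and without the PDV, MSCP1 and B9ras arrays, and all settings of the Spretus-cross index, were chosen only after seeing the data. No paired analysis was possible because replicate numbers were given in the order of deposition. Where no reason is given, the cause was not tested. Signal near background limits what a fold change can show in lines that lack a transcript.

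For spindle against non-spindle, the 8 genes became 5 with the mean of a gene's probe sets, 16 with every probe set on its own, 3 with no filter, 2227 with array weights (1299 higher, 928 lower), and 5 at 2-fold. They became 1 with name families averaged, 2 with the family as a random block, 0 with conflicting lines placed by cell type label, 98 with B9Smad placed by its flag, 0 with close arrays averaged, 1603 without Spretus-cross lines, and 1954 without MSC12, MSC11B and MSC7A. Beside the limma counts of 0, 1930 genes with conflicting lines placed by cell type label and 1335 with close arrays averaged had an unadjusted p under 0.05. Leaving out 1 line gave 2 to 471.

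For non-spindle against keratinocyte, 255 became 163 with conflicting lines placed by cell type label and 150 with close arrays averaged, and leaving out 1 line gave 147 to 352. For spindle against keratinocyte, 676 became 1043 probe sets on their own and 323 with close arrays averaged, and leaving out 1 line gave 258 to 765. For the Spretus cross, array weights gave 304 in place of 0 and leaving out 1 line 0 to 163.

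The index difference of -2.87 passed its exact test with B9Smad placed by its flag (-2.91, p = 0.0497) and without Spretus-cross lines (-4.99, p = 0.000583), and ran from -3.41 to -2.48 with 1 line left out (p from 0.0212 to 0.118). Without the 3 lines the index difference was -4.67 (exact p = 0.00035), which is no test, since they were chosen for low values of genes in the index. The setting without Spretus-cross lines leaves out the same 3 lines, so its p is no separate test. Of the non-spindle lines it keeps, all but E4 are joined by name family or close arrays, which the exact test takes as independent. The index difference for the Spretus cross, -4.23, was -0.946 without the 3 lines (exact p = 0.5), which is no test either, since the choice of these lines fixes it. It ran from -5.291 to -3.482 with 1 line left out (exact p from 0.0152 to 0.0801). Lists called by camera, 8, 13, 10 and 15 in the 4 comparisons, fell to 0 in each with an estimated correlation, and fry called 0 in all but spindle against keratinocyte, where it called 7. Lce1a1 turned from -1.58 to 0.033 without NK and was -3.183 without C5N. No other named gene that was called turned its direction in the settings where directions were compared. Directions were not compared with every probe set on its own or at the 2-fold minimum. The other settings run kept each count within 1.5 times, and the index of spindle against non-spindle lines on the same side of its threshold.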

Other observations

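The lines outside the comparisons held values of their own. The papilloma line P6 had an index of 2.85, near the keratinocyte lines at 2.32 and 3.06, with Cdh1 at 11.38 and Krt14 at 14.35. Its Hmga2 value of 10.49 and Twist2 value of 7.03 lay above both keratinocyte lines, where Hmga2 was at 4.98 and 8.03 and Twist2 at 4.87 and 4.99. The keratinocyte line with conflicting labels had an index of 1.15, Twist2 at 5.02 and Hmga2 at 10.86. B9Smad, labelled as spindle but not by its flag, had an index of -0.06 with Cdh1 at 8.49 and Krt14 at 13.75. Of the lines with no stated spindle state, 2945CA had an index of -3.78 with Cdh1 at 3.40 and Epcam at 4.35, and MSCb1 an index of -1.65 with Cdh1 at 10.02 and Epcam at 7.34.

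Sex-linked transcripts differed between lines of related names. Xist was at 11.71 in PDV and 5.73 in PDVC57. B9 and B9rassmad had Xist at 10.73 and 11.30 together with the Y-linked Eif2s3y at 8.80 and 7.18, whereas B9ras and B9Smad had Xist at 11.86 and 11.25 with Eif2s3y at 3.17 and 3.35. MSC11B also had both, with Xist at 11.16 and Eif2s3y at 9.59. MSCP5 had Eif2s3y at 8.25 with Kdm5d at 3.08.

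Other divisions of the lines were drawn to ask how often they give such counts. The test that keeps related lines together was chosen only after the result was seen. For spindle against non-spindle lines, 2 of 100 divisions of single lines, the real one included, gave 8 or more genes, and the highest of the others gave 16. Those divisions take related lines as independent. When lines of 1 name family and close arrays were kept together in 11 blocks, 68 of all 170 divisions gave 8 or more genes and the highest gave 2946. So chance is not excluded for the 8 genes, and these high counts point to a structure of the samples. The 3 highest counts came from divisions that set the block of PDV, PDVC57, MSCP1, B9, B9ras and B9rassmad, with 1 further line, against the rest.

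For the Spretus cross the same test decides nothing, since 100 of 100 divisions must give 0 or more genes. The highest other division gave 1150 genes, which points to a structure of the samples within the non-spindle lines. It put MSC12, MSC11B and MSC7A on the same side, but 18 of the 19 drawn divisions that did so gave 0 genes, so these 3 lines alone do not set that count.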
